A study of Homo sapiens with 16 samples.

How the data were processed

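The samples were PC9 cells, an established human lung adenocarcinoma line that carries an activating EGFR mutation. Chromatin was profiled by CUT&RUN, in which an antibody directs a nuclease to cut the DNA around its target so that the released fragments can be sequenced. The labels give 16 samples in 8 groups of 2 replicates: wild type and METTL7A knockout, each untreated or treated with osimertinib, and each with an antibody against TOP2B or against histone H2A. Per the labels' protocols, treatment ran for 6 to 8 weeks with the dose raised from 100 nM, libraries were made from 2.5 ng of chromatin, and 20000000 paired-end reads per library were planned. Nothing in the labels says whether the replicates came from separate cultures.

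Per the submitters' processing notes, the tools were Trimmomatic, FastQC, Bowtie2 2.4.2, SAMtools 1.16, deepTools 3.5.1, bedtools 2.30 and SEACR, and the genome build was GRCh37. The versions of Trimmomatic, FastQC and SEACR, the mode and control of the peak caller, the treatment of duplicate reads and any list of excluded regions are not given in the sources used here. The deposited results used here were 4 peak lists, 1 for each combination of genotype and treatment with the TOP2B antibody, each named by the authors as an intersection of peaks. The 8 samples of the H2A antibody had no peak list here and were not analysed. The lists have no header, so each column was identified from its values.

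Each entry of a list is an interval with a chromosome, a start and an end, followed by values in the layout of a SEACR peak. The area of the called peak is a deposited score, the signal summed over the bases of the peak. The maximum of the called peak is a deposited signal, the highest coverage within it, and a text field gives the region of that maximum. Starts and ends lie on a grid of 50 bp bins except at the end of a sequence. Within each list, 100% of the maxima were whole multiples of 1 step, to a tolerance of 0.01 steps. The step was 0.0392 in untreated wild type, 0.0723 in untreated knockout, 0.0535 in treated wild type and 0.0379 in treated knockout. The scaling behind the step is not given in the sources used here. If 1 step were 1 read in a CPM scaling, the libraries would hold 25489396, 13833895, 18708284 and 26352128 reads in that order, but the depth of the libraries is unknown from the lists. The lowest maximum was 5, 2, 5 and 4 steps in that order and the median maximum 12, 5, 11 and 8 steps, so the lists differ in the lowest signal that entered them.

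Area and maximum belong to a called peak, not to the interval beside which they stand. Several intervals of a list can share the same area, maximum and region of the maximum, as arises when a broad peak of 1 replicate is intersected with narrower peaks of the other. The region of the maximum lay outside the interval for 51.8% of the intervals in untreated wild type, 11.9% in untreated knockout, 70.2% in treated wild type and 50.9% in treated knockout. The maxima were therefore used to rank and describe called peaks within a list, and across lists only for the change of maxima between overlapping intervals relative to other windows of the same comparison.

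All results are reported by position on GRCh37, counted from 1. Comparisons of promoters and gene lists planned before the data were examined were not run, because an annotation of GRCh37 was not used here and positions were not converted between builds. The METTL7A locus was for the same reason not examined, so the genotype labels were not checked. The comparisons were knockout against wild type within each treatment and osimertinib against untreated within each genotype. An interval had a counterpart when an interval of the other list overlapped it by at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals, and ratios of shares carry exact conditional 95% intervals from the 2 counts. These intervals cover counting error only: neighbouring intervals are not independent, and each condition has 1 list made from 2 replicate libraries, so there was no replicate of a list, no spread between replicates and no test between conditions. Overlaps are set beside 100 random placements of the intervals within their chromosomes and beside 100 shifts of a whole list by 20 to 500 kb, which keep the regional density.

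Regional density was counted by interval midpoints in windows of 1 Mb. Windows with at least 20 intervals in either list of a comparison were examined, and a share ratio of at least 2 in either direction, with 0.5 intervals added to each count, was counted as a difference. Runs of neighbouring 5 Mb windows past the same ratio were joined into segments; this joining was chosen after the data had been examined. A window without an interval is one where no peak entered the list, which is not a measurement of zero signal. Where 1 of the counts was 0, the exact 95% bound of the ratio is given in place of the ratio. Before the data were examined, the rule for named positions was fixed as the 3 windows of 1 Mb with the largest rise and the 3 with the largest fall in share per comparison, and the 3 intervals without a counterpart with the highest maximum per list. Segments and chromosomes named in addition were chosen after their values had been seen. Named windows and segments were picked for large ratios in the same lists. Their 95% intervals take no account of this selection and may lie too far from a ratio of 1.

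Overlap with other definitions, merging within 1 kb, lists of equal length, the upper 50% of maxima, autosomes and X alone, removal of the densest 1% of windows, windows of 5 Mb and summed length were tried as alternatives. Counting each called peak as 1 was added after the data had been examined. The procedure was tested on simulated data made from the untreated wild-type list: over 15280 intervals the overlap differed from a direct count in 0 cases. Of 225 windows all 40 with a planted loss were found, with 0 calls among the 185 unchanged ones. The planted losses were well past the 2-fold limit and fell on intervals at random. Gains, smaller losses, split peaks and differences of width or threshold were not simulated. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.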

Results

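TOP2B, the beta isoform of DNA topoisomerase II, was profiled in PC9 lung adenocarcinoma cells with and without METTL7A, a gene of the methyltransferase-like family. PC9 growth depends on mutant EGFR, the receptor tyrosine kinase that osimertinib inhibits, and the treated cells were kept under rising osimertinib doses for 6 to 8 weeks. The series concerns priming for drug resistance and gene amplification, and its design sets genotype against treatment. Each of the 4 conditions had 2 replicate TOP2B libraries and 1 list of peak intervals made from them. Values are therefore given per list, with 95% intervals for counting error only, and no difference between conditions could be set against a spread between replicates.

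Untreated cells had the longer lists and the wider intervals. The untreated wild-type list held 15281 intervals with a median width of 2600 bp (interquartile range 1950 to 3600) over 48.6 Mb. The untreated knockout list held 12493 intervals with a median of 1650 bp (1250 to 2200) over 23.3 Mb. Under osimertinib the wild-type list held 9655 intervals with a median of 1200 bp (950 to 1450) over 12.1 Mb, and the knockout list held 7493 intervals with a median of 1150 bp (800 to 1550) over 9.38 Mb. The order of the untreated lists depended on how peaks were counted. In untreated wild type, 49.96% of the intervals were pieces of a called peak that had been split, against 3.34% in untreated knockout, 49.9% in treated wild type and 33.7% in treated knockout. Counting each called peak as 1 gave 10488 peaks in untreated wild type and 12284 in untreated knockout, so that the ratio of knockout to wild type changed from 0.818 to 1.17. Under osimertinib the same ratio was 0.776 by intervals and 0.91 by called peaks.

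Intervals were concentrated in a limited set of chromosome regions in every list. In untreated wild type, chromosome 20 held 17.4% of the intervals (95% interval 16.8 to 18), chromosome 2 held 12.8% and chromosome 7 held 10.7% (10.2 to 11.2). Shares of chromosomes were not set against their length, so they do not rank chromosomes by density. The untreated knockout list had 20.3% on chromosome 20 (19.5 to 21) and 10.9% on chromosome 7 (10.3 to 11.4), and the treated knockout list had 19.9% (19 to 20.8) and 15.4% (14.6 to 16.3). The treated wild-type list differed from the others, with 5.83% on chromosome 20 (5.37 to 6.32), 3.79% on chromosome 7 (3.42 to 4.19), 16.8% on chromosome 5 and 10.9% on chromosome 17 (10.3 to 11.6). Chromosome 17 held 2.98% of the untreated wild-type list (2.72 to 3.27), 0.808% of the untreated knockout list (0.659 to 0.981) and 0.827% of the treated knockout list (0.635 to 1.06). Counts were correlated across the 1423 windows of 1 Mb with an interval in at least 1 of the 4 lists. Windows empty in all lists were left out, and the correlations depend on that choice. Spearman's rho of interval counts was 0.787 between untreated wild type and untreated knockout, 0.728 between untreated and treated knockout, 0.409 between untreated and treated wild type, and 0.282 between the treated lists. Pearson's r was 0.925, 0.934, 0.419 and 0.312 in the same order. These correlations run across windows of single lists, and windows are not independent replicates.

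**Figure D1:**
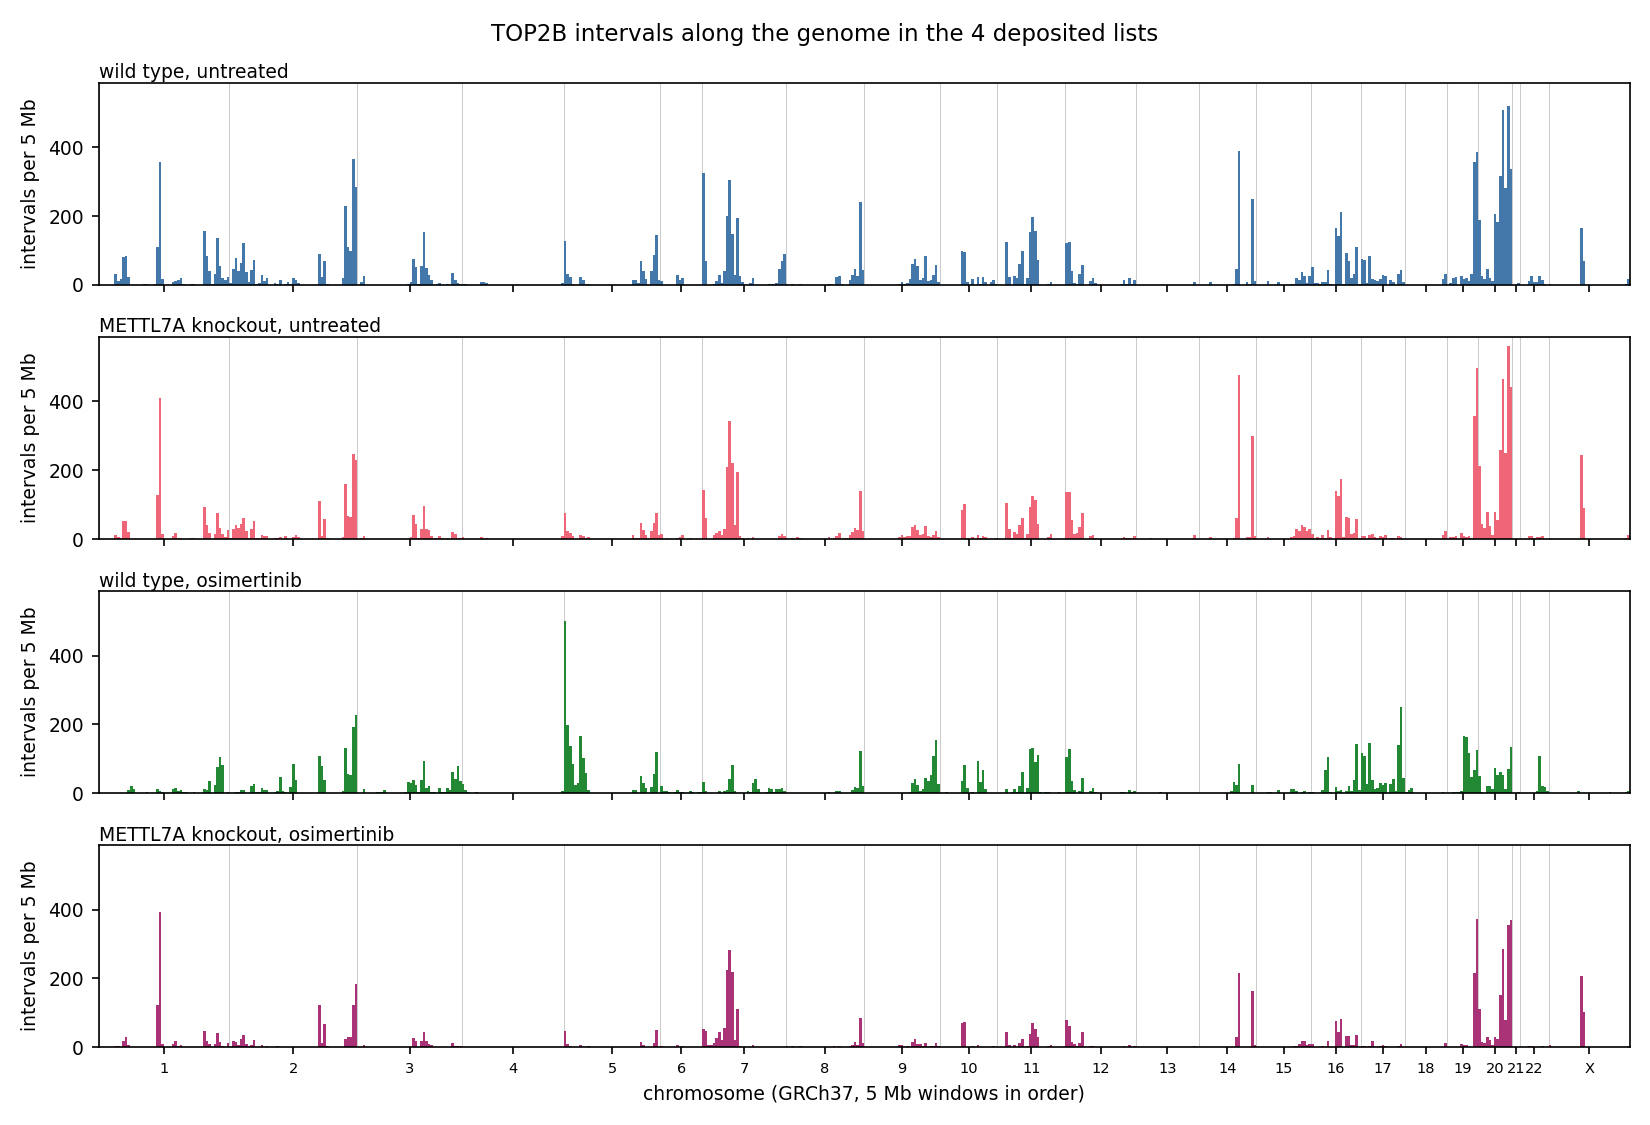
Number of TOP2B intervals per 5 Mb window (vertical axis, intervals) along the chromosomes in genome order (horizontal axis, GRCh37), with 1 panel for each of the 4 lists. The treated wild-type list had 1302 intervals in the first 45 Mb of chromosome 5, where the other lists had 226, 155 and 73.

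The comparison of untreated knockout with untreated wild type asks what loss of METTL7A changes in TOP2B occupancy without drug. Regional profiles were similar, and the regions that differed lay mainly on chromosomes 17, 7 and 20. The first 10 Mb of chromosome 17 held 148 intervals in wild type and 17 in the knockout, a ratio of list shares of 0.14 (95% interval 0.0797 to 0.233). From 145 Mb to the end of chromosome 7 the counts were 206 and 34, a ratio of 0.202 (0.136 to 0.291). Chromosome 20 differed in both directions, with 389 and 135 intervals between 30 and 40 Mb (0.424, 0.346 to 0.518) and 111 and 196 between 5 and 25 Mb (2.16, 1.7 to 2.75). The last of these ratios was 1.68 by called peaks.

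By the rule for named windows, the share in the knockout exceeded that in wild type most at 64 to 65 Mb of chromosome X, with 80 and 147 intervals (2.25, 1.7 to 2.99), and at 17 to 18 Mb (22 and 39) and 5 to 6 Mb (13 and 23) of chromosome 20. The log2 ratio at 5 to 6 Mb of chromosome 20 was 1.09, and 0.57 by called peaks, which is under 2-fold. At 64 to 65 Mb of chromosome X it was 1.16, and 0.87 by summed length and 0.86 in the 5 Mb window, also under 2-fold. It was lowest against wild type at 18 to 19 Mb of chromosome 17, with 23 and 0 intervals (upper bound of the ratio 0.213). It was also low at 79 to 80 Mb of chromosome 17 (27 and 1) and at 158 to 159 Mb of chromosome 7 (20 and 1). Of 231 windows examined, 31 had a share at least 2-fold lower in the knockout and 3 at least 2-fold higher, 14.7% in all, and 24.8% when each called peak was counted as 1. By number of intervals, 51 windows were at least 2-fold lower in the knockout and 0 at least 2-fold higher. Of the wild-type intervals, 64.9% (64.1 to 65.6) had no counterpart in the knockout, and of the knockout intervals 46.3% (45.4 to 47.2) had none in wild type. The 35.1% of wild-type intervals with a counterpart compare with a mean of 5.23% for intervals placed at random within their chromosomes and 21% for shifts of the whole list. Requiring an overlap of 50% of both intervals raised the knockout share without a counterpart to 84.7%.

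Intervals without a counterpart that belonged to the highest called peaks exceeded the median maximum of their list by a few fold. The maximum is that of the called peak, which can extend beyond the interval and give several intervals. In wild type these intervals lay at 33293751 to 33294750 of chromosome 16 (2.5 times the list median), 54985601 to 54991350 of chromosome 19 (2.17 times) and 102093851 to 102097300 of chromosome 14 (2.08 times). In the knockout they lay at 49433951 to 49435400 of chromosome 5 (3.6 times), 42599551 to 42600450 of chromosome 10 (3.2 times) and 108297401 to 108297900 of chromosome X (2.8 times).

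In wild type, the comparison of osimertinib with no treatment addresses TOP2B occupancy in cells that had grown under the drug. Whole segments of chromosomes held a different share of the intervals. The first 45 Mb of chromosome 5 went from 226 to 1302 intervals, a ratio of shares of 9.12 (7.91 to 10.5), and 30 to 50 Mb of chromosome 19 from 80 to 493 (9.75, 7.69 to 12.5). Chromosome 17 from 70 Mb to its end went from 82 to 436 (8.42, 6.63 to 10.8), and chromosome 9 from 120 Mb to its end from 120 to 379 (ratio 5.0). Other segments held fewer: 1809 and 248 intervals at 35 to 60 Mb of chromosome 20 (0.217, 0.189 to 0.248), 543 and 57 at 40 to 55 Mb of chromosome 7 (0.166, 0.124 to 0.219), 466 and 17 at 110 to 120 Mb of chromosome 1 (0.0577), and 234 and 0 at 60 to 70 Mb of chromosome X (upper bound 0.0251). By called peaks the ratios for chromosomes 5, 20 and 1 were nearer to equality, at 5.96, 0.332 and 0.0881.

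Of 307 windows examined in this comparison, 91 had a share at least 2-fold higher under osimertinib and 115 at least 2-fold lower, 67.1% in all. By number of intervals, 82 windows were at least 2-fold higher, although the treated list was shorter, and 155 at least 2-fold lower. The largest differences by the rule were windows with intervals in 1 of the 2 lists only. Those with higher shares under osimertinib were 32 to 33 Mb of chromosome 19 with 0 and 57 intervals (lower bound of the ratio 23.7), 37 to 38 Mb of chromosome 22 with 0 and 39 (16.0), and 78 to 79 Mb of chromosome 11 with 0 and 21 (8.24). Those with lower shares were 68 to 69 Mb of chromosome 7 with 101 and 0 intervals (upper bound of the ratio 0.0589), 116 to 117 Mb of chromosome 1 with 87 and 0 (0.0686) and 64 to 65 Mb of chromosome X with 80 and 0 (0.0747).

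Of the untreated wild-type intervals, 85.2% (84.6 to 85.7) had no counterpart under osimertinib, and 71.3% (70.4 to 72.2) of the treated intervals had none in the untreated list. The 14.8% with a counterpart compare with 2.14% for random placement and 7% for shifts of the whole list. The 3 untreated intervals without a counterpart from the highest called peaks were on chromosome 7, the chromosome that carries EGFR, at 55516051 to 55521700 (2.75 times the list median), 55068351 to 55073100 and 55074151 to 55077600 (both 2.42 times). The 1 Mb window at 55 Mb of chromosome 7 still held 95 untreated and 69 treated intervals, a smaller fall than that of the whole list. The position of EGFR itself was not examined. Treated intervals without an untreated counterpart were highest at 49434001 to 49434500 of chromosome 5 (4.18 times the list median), 772901 to 774250 of chromosome 5 (2.36 times) and 21233551 to 21234700 of chromosome 17 (2.27 times). The first of these lies within the interval named on chromosome 5 for the untreated knockout.

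**Figure D2:**
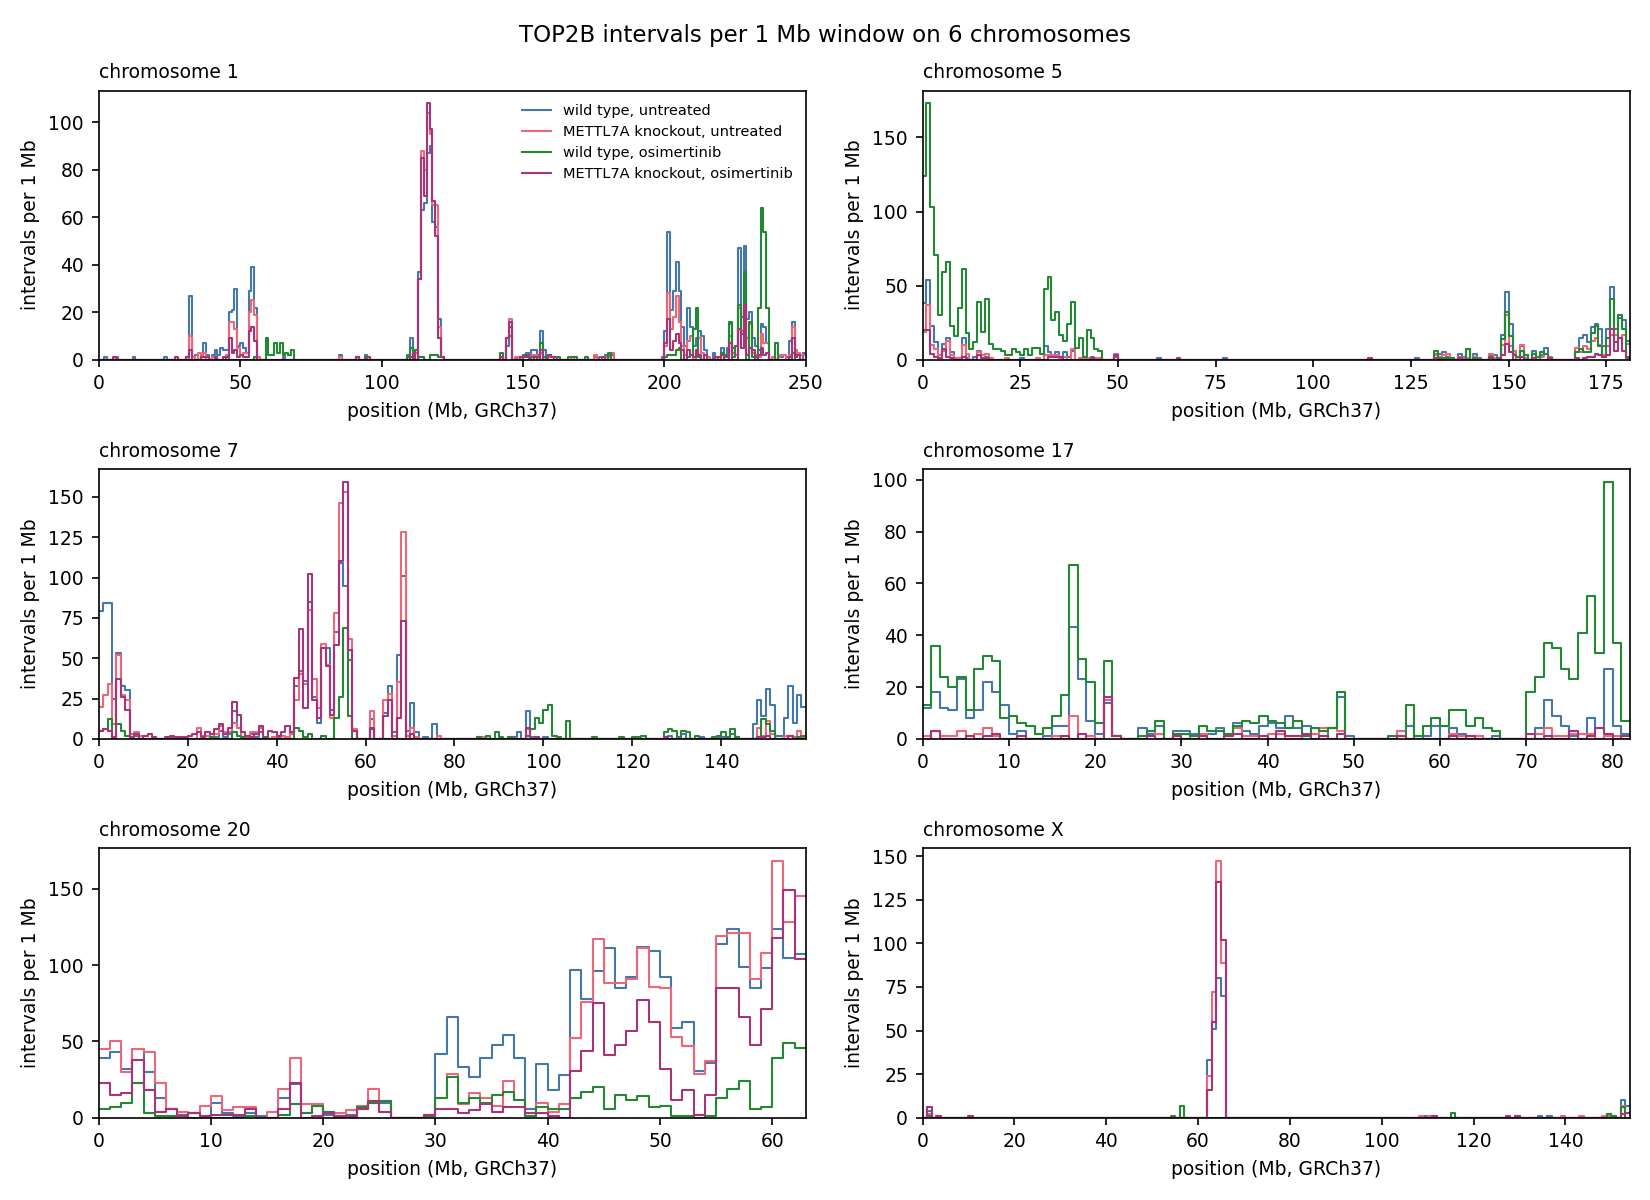
Number of TOP2B intervals per 1 Mb window (vertical axis, intervals) by position (horizontal axis, Mb, GRCh37) on chromosomes 1, 5, 7, 17, 20 and X, with 1 line for each of the 4 lists. At 64 to 65 Mb of chromosome X the treated wild-type list had 0 intervals, against 80 in untreated wild type, 147 in untreated knockout and 135 in treated knockout.

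In the knockout, the same comparison showed fewer regional differences in share. Of 158 windows examined, 5 had a share at least 2-fold higher under osimertinib and 16 at least 2-fold lower, 13.3% in all. By number of intervals, without regard to the shorter treated list, 1 was at least 2-fold higher and 61 at least 2-fold lower. The only segment with a higher share was 25 to 45 Mb of chromosome 7, with 83 and 149 intervals (2.99, 2.27 to 3.96). Among segments with a lower share, 220 to 225 Mb of chromosome 2 held 160 and 23 intervals (0.24, 0.148 to 0.372) and 165 to 175 Mb of chromosome 5 held 70 and 15 (0.357). The first 45 Mb of chromosome 5, with the higher share in treated wild type, held 1.24% of the untreated knockout list (1.05 to 1.45) and 0.974% of the treated one (0.764 to 1.22).

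The named windows of the knockout comparison were 30 to 31 Mb (10 and 23 intervals, 3.83, 1.76 to 9.03), 45 to 46 Mb (40 and 68, 2.83, 1.89 to 4.3) and 44 to 45 Mb (24 and 38) of chromosome 7 for higher shares under osimertinib. For lower shares they were 53 to 54 Mb of chromosome 20 (29 and 2, 0.115, 0.0133 to 0.455) and 223 to 224 Mb (49 and 6) and 222 to 223 Mb (51 and 7) of chromosome 2. In 5 Mb windows the log2 ratio around 45 to 46 Mb of chromosome 7 was 0.84 and that around 53 to 54 Mb of chromosome 20 was -0.92, both under 2-fold. Of the untreated knockout intervals, 76.6% (75.9 to 77.4) had no counterpart under osimertinib, and 56.3% (55.2 to 57.5) of the treated intervals had none in the untreated list, a share that became 85.3% when an overlap of 50% of both intervals was required. The 23.4% with a counterpart compare with 2.32% for random placement and 12.5% for shifts of the whole list. Among untreated intervals without a treated counterpart, the highest were at 42599551 to 42600450 of chromosome 10 (3.2 times the list median), 108297401 to 108297900 of chromosome X (2.8 times) and 57019651 to 57021600 of chromosome 19 (2.4 times). Among treated intervals without an untreated counterpart, they were at 64723801 to 64723900 and 64758451 to 64759400 of chromosome X (both 2.75 times) and 116040501 to 116041400 of chromosome 1 (2.62 times).

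Knockout and wild type under osimertinib had the lowest correlation of regional counts among the 4 pairs compared. The first 45 Mb of chromosome 5 held 1302 intervals in treated wild type and 73 in the treated knockout (0.0722, 0.0563 to 0.0915), and 30 to 50 Mb of chromosome 19 held 493 and 14 (0.0366). In the other direction, 25 to 70 Mb of chromosome 7 held 155 and 1009 intervals (8.39, 7.08 to 10), chromosome 20 from 40 Mb to its end 330 and 1242 (4.85, 4.29 to 5.49), and 110 to 120 Mb of chromosome 1 held 17 and 516 (39.1, 24.2 to 67.7, and 24.2 by called peaks). Of 212 windows examined, 70 had a share at least 2-fold higher in the knockout and 105 at least 2-fold lower, 82.5% in all. By number of intervals, 65 were at least 2-fold higher and 113 at least 2-fold lower.

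The named windows with higher shares in the treated knockout were 64 to 65 Mb of chromosome X (0 and 135 intervals, lower bound of the ratio 46.5), 116 to 117 Mb of chromosome 1 (0 and 108, lower bound 37.1) and 65 to 66 Mb of chromosome X (0 and 102, lower bound 35.0). Those with lower shares were 17 to 18 Mb of chromosome 17 (67 and 0, upper bound of the ratio 0.0729), 31 to 32 Mb of chromosome 5 (48 and 0, upper bound 0.103) and 80 to 81 Mb of chromosome 10 (43 and 0, upper bound 0.115). Of the treated wild-type intervals, 89.5% (88.9 to 90.1) had no counterpart in the treated knockout, and 86.6% (85.8 to 87.4) of the treated knockout intervals had none in treated wild type. The 10.5% with a counterpart compare with 0.955% for random placement and 3.73% for shifts of the whole list. Relative to shifted lists this overlap was 2.82 times as high, more than the 1.67 to 2.12 times of the other comparisons. With a reciprocal overlap of 50% the shares without a counterpart were larger for treated against untreated wild type (97.1 and 95.4%) than for the treated lists (95.4 and 94.1%). That setting also depends on width, and median widths were 2600 bp in untreated wild type but 1200 and 1150 bp in the treated lists. It therefore does not rank the comparisons by position alone. The highest treated wild-type intervals without a knockout counterpart were at 49429801 to 49430650 of chromosome 5 (3.82 times the list median) and at 145025201 to 145026000 and 145031751 to 145033200 of chromosome 1 (both 2.64 times). The highest treated knockout intervals without a wild-type counterpart were at 46409101 to 46409950 of chromosome 16 (22.4 times the list median) and at 55298901 to 55299850 and 55301901 to 55302450 of chromosome 7 (both 2.75 times).

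**Figure D3:**
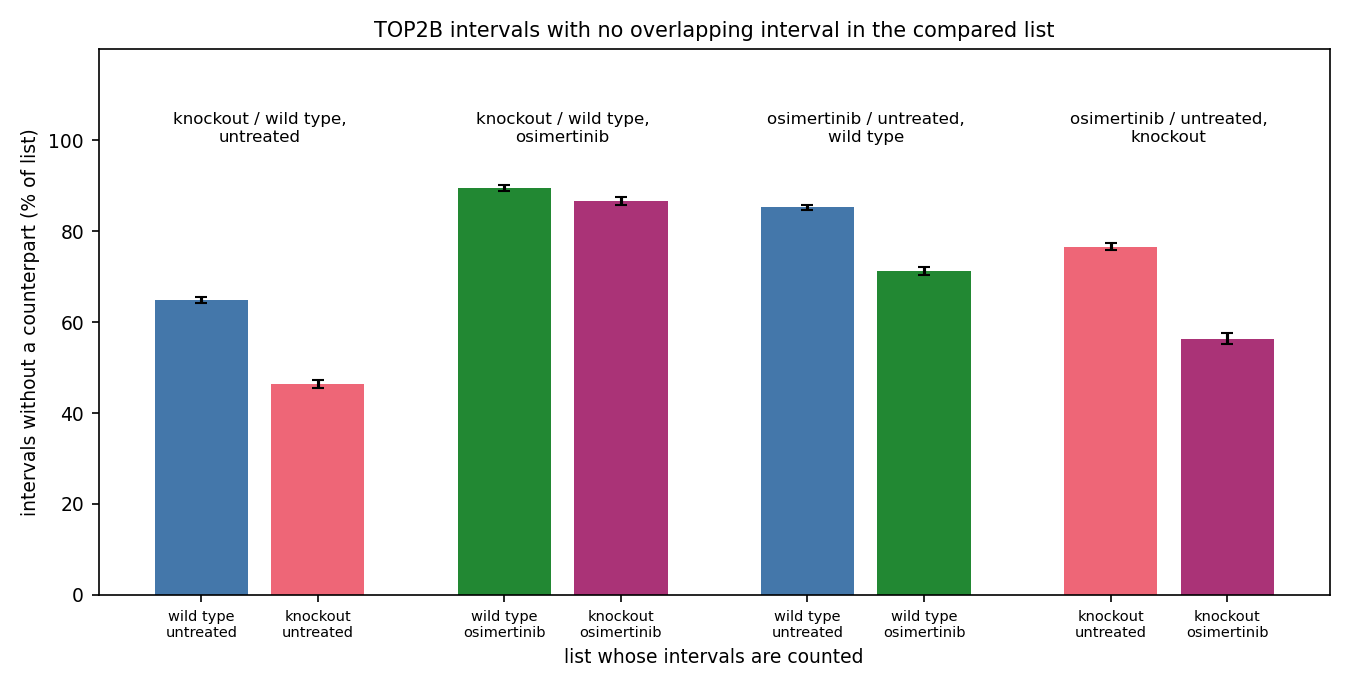
Share of TOP2B intervals without an overlapping interval in the compared list (vertical axis, % of the list), with 1 bar for each list of the 4 comparisons and exact 95% binomial intervals for counting error as error bars. The lowest bar is the untreated knockout against untreated wild type at 46.3% and the highest the treated wild type against the treated knockout at 89.5%.

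A larger share of untreated intervals had a treated counterpart in the knockout than in wild type. The share was 23.4% in the knockout (22.6 to 24.1) and 14.8% in wild type (14.3 to 15.4), a difference of 8.52 percentage points (7.58 to 9.46, counting error only). The knockout share was higher in each of 4 classes of width. Among intervals of up to 1500 bp the shares were 13.9% (13 to 14.9) in the knockout and 6.24% (5.22 to 7.39) in wild type, and among intervals over 3000 bp they were 59.7% (56.9 to 62.4) and 22.4% (21.3 to 23.5). Shifts of a whole list, which keep the regional density, gave 12.5% in the knockout and 7% in wild type, so that relative to shifted lists the share was lower in the knockout (1.87 times) than in wild type (2.12 times). The difference ranged from 4.73 percentage points without the densest windows to 13.2 with lists of equal length, where ties of the maximum were cut in order of chromosome name. Whether the effect of treatment differed between genotypes could not be tested with 1 list per condition.

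Wild-type intervals absent from the knockout were also often absent under osimertinib, but most wild-type intervals were absent in each of these comparisons. Of 15281 untreated wild-type intervals, 9912 had no counterpart in the untreated knockout, 13012 had none in treated wild type and 8758 had none in either. Independent lists would give 8440 and independence within deciles of the deposited maximum 8587, so the observed number was 1.02 times the latter. It could be at most 9912, so the ratio could not rise far above 1. A ratio near 1 therefore does not show that the absences were unrelated. Both comparisons share the untreated wild-type list, and part of the excess may come from that.

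Few positions were shared by all conditions. In untreated wild type, 634 intervals (4.15%, 3.84 to 4.48) overlapped intervals of every other list. The corresponding numbers were 561 in untreated knockout (4.49%), 555 in treated wild type (5.75%) and 533 in treated knockout (7.11%). Intervals that overlapped no other list made up 51.8% of untreated wild type, 39.3% of untreated knockout, 64.7% of treated wild type and 29.5% of treated knockout.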

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

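The tests of a common threshold or depth, of whole-segment signal under osimertinib in wild type, of an exchange of the treated lists and of split peaks were chosen after the results they address had been seen. On 5 chromosomes the share of the list moved in opposite directions under osimertinib in the 2 genotypes, beyond counting error in each. Shares are relative to lists that shortened under osimertinib (to 0.632 of the intervals in wild type and 0.6 in the knockout), and of these 5 only chromosome 5 went opposite ways by number of intervals. The difference between genotypes was not tested, since each condition has 1 list. On chromosome 5 the treated share over the untreated share was 3.78 in wild type and 0.685 in the knockout, with 679 to 1619 and 420 to 172 intervals. On the other 4 of them the number fell in both genotypes. The share ratio on chromosome 7 was 0.354 and 1.41 (1636 to 366 and 1358 to 1155 intervals), and on chromosome X 0.127 and 1.54 (262 to 21 and 351 to 324). It was 0.531 and 1.24 on chromosome 1 (1372 to 461 and 1068 to 795), and 1.24 and 0.794 on chromosome 12 (478 to 375 and 522 to 249).

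The regional difference between treated and untreated wild type goes in both directions, with 82 windows of 1 Mb that hold at least 2 times as many intervals in the shorter list, which argues against 1 threshold or depth acting on the whole list. The deposited maxima of overlapping intervals moved with the window ratios (Spearman's rho 0.789 over 185 windows). The maximum belongs to the whole called peak. Its region lay outside the interval for 51.8% of untreated and 70.2% of treated wild-type intervals. A longer called peak can give both more pieces and a higher maximum. This value alone therefore cannot separate splitting by the caller from a change of signal. The windows measured include 46 of the 115 windows with a lower share, where 6.27% of the untreated intervals were measured. With each called peak counted as 1, 59.5% of windows differed at least 2-fold in share, and 69.4% by summed length, against 67.1% by intervals. Over all comparisons, the 136 segments kept their direction by called peaks, and 124 stayed at least 2-fold different. These values argue against split peaks as the source of most of the regional difference. Whether the signal itself changed stays open, both in the windows measured and in those not measured. Window ratios 10 Mb apart correlated by 0.544 over 59 pairs, above the highest of 1000 permutations (0.444). At 20 Mb they correlated by 0.236, where permutations reached 0.398. The permutations moved single windows freely, although ratios 1 Mb apart correlated by 0.913. The pairs are therefore not independent, and the range of the permutations may be too narrow. A change of signal over whole chromosome segments would give such a correlation, but the permutations do not separate it from shorter runs of windows. A hypothesis is that the number of DNA copies of these segments differed in the treated population, and TOP2B occupancy that changed over long segments may give the same pattern. The H2A libraries, which bear on copy number, were not analysed here, and a list made from other cells and, untested, the treatment itself stay open.

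An exchange of the treated lists also stays open for this pattern, because both treated lists correlated only slightly better with the untreated list of their own genotype (Spearman's rho higher by 0.038 in the knockout and 0.095 in wild type). Other values run both ways. Pearson's r of the treated knockout was 0.934 with untreated knockout and 0.825 with untreated wild type. For treated wild type it was 0.419 with untreated wild type and 0.334 with untreated knockout. The first 20 Mb of chromosome 17 held 28 intervals in untreated knockout and 11 in treated knockout, against 237 and 397 in wild type. From 145 Mb to the end of chromosome 7, treated wild type held 0.331% of its list. That is nearer to untreated knockout (0.272%) than to untreated wild type (1.35%). The treated knockout held 0.0801% there, also nearer to untreated knockout.

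In the untreated knockout, the window ratios against wild type correlated by 0.429 at 10 Mb over 43 pairs, where permutations reached 0.542, by 0.73 at 1 Mb against 0.264, and by -0.375 at 20 Mb over 31 pairs. The value at 10 Mb lies within the range of the permutations, so signal over whole segments and more local differences cannot be told apart by it. The maxima of overlapping intervals did not move with the window ratios (rho -0.156 over 211 windows), and the 20 windows with a lower share and enough overlapping intervals had a median log2 change of maxima of -0.42 (SD 0.22), against -0.38 (SD 0.19) in the 189 windows without a 2-fold difference. Maxima were measured only on intervals of both lists, which were 13.2% of the wild-type intervals in the 31 windows with a lower share, so whether intervals were lost at the calling limit without a change of regional signal stays open. The knockout itself stays open as an untested biological explanation. A different number of DNA copies of these regions in the knockout cells stays open as well and was not tested. Chromosome 17 as a whole held 2.98% of the untreated wild-type list. It held 0.808% of the untreated and 0.827% of the treated knockout list.

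The larger number of intervals in untreated wild type than in untreated knockout turned around when each called peak was counted as 1, to a ratio of knockout to wild type of 1.17. The splitting of broad called peaks by the intersection is a candidate explanation for the difference in interval number. Why 7635 intervals came from split peaks in wild type and 417 in the knockout was not tested.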

How the results depend on the processing

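Counting each called peak as 1 was chosen after the data had been examined, and the other alternatives before. No paired analysis was possible because each condition has 1 list made from both replicates, and for the same reason no replicate could be left out. Alternatives for promoters and gene lists were not run, as an annotation of GRCh37 was not used here. Among alternative values of the main results, 41 lay within counting error or within 1.5 times a count, and 62 moved further. A reversal was defined only for the difference in retained intervals, which kept its direction in each setting. The order of the untreated lists by number turned with called peaks (knockout over wild type 0.818 and 1.17). By called peaks all 136 segments kept their direction and 124 stayed at least 2-fold different. For the 24 named windows, all 72 values under windows of 5 Mb, summed length and called peaks kept their direction, and 5 of them were under 2-fold. Autosomes and X alone moved none of the 14 values examined. This was fixed in advance, because that setting left out only the mitochondrial sequence. It held 1 interval in each list except treated wild type, which had 2. The depth of the libraries is unknown from the lists, which limits every count of intervals.

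The shares without a counterpart follow in this order: untreated wild type against knockout (64.9%), untreated knockout against wild type (46.3%), treated wild type against knockout (89.5%), treated knockout against wild type (86.6%), untreated against treated wild type (85.2%), treated against untreated wild type (71.3%), untreated against treated knockout (76.6%) and treated against untreated knockout (56.3%). A reciprocal overlap of 50%, a stricter definition by construction, gave 87.5, 84.7, 95.4, 94.1, 97.1, 95.4, 91.2 and 85.3%. Intervals of very unlike width cannot meet this definition. An interval of the other list within 1 kb, a looser one, gave 58.5, 37.7, 85.9, 81.2, 81.7, 64.9, 69.6 and 44.9%. The upper 50% by maximum gave 48.1, 38.3, 87.1, 84.6, 81.6, 67.7, 69.2 and 44.5%. Lists shortened to 7493 intervals gave 61.1, 51.0, 88.4, 88.5, 84.7, 79.6, 71.5 and 66.7%. In this setting and in the upper 50%, intervals tied at the cut were kept in order of chromosome name and position. Their chromosome shares may therefore be skewed. Leaving out the 15 densest of 1424 windows gave 69.1, 52.1, 92.4, 88.3, 86.0, 75.2, 81.3 and 63.2%. Called peaks counted as 1 gave 63.9, 42.2, 87.9, 83.1, 80.8, 68.2, 75.6 and 57.8%. Merging within 1 kb moved the untreated knockout against wild type to 47.7% and untreated against treated wild type to 84.5%. Apart from the first 2 of these settings, the cause was not tested.

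The difference in retained intervals between knockout and wild type (8.52 percentage points) was 5.88 with reciprocal overlap, 12.1 within 1 kb, 12.4 for the upper 50% by maximum, 13.2 with equal lengths, 7.48 after merging, 4.73 without the densest windows and 5.18 by called peaks, so the knockout share stayed higher in each, although relative to shifted lists it was lower (1.87 against 2.12 times). The ratio of wild-type intervals absent from both lists to independence (1.02) was 1.002 with reciprocal overlap and 1.05 for the upper 50% by maximum. Windows with a 2-fold difference were 20.7% with windows of 5 Mb and 24.8% by called peaks for the untreated knockout against wild type (14.7%), 75.2% with windows of 5 Mb for the treated knockout against wild type (82.5%), and 59.5% by called peaks for treated against untreated wild type (67.1%). The cause was not tested.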

Other observations

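Several chromosomes held few TOP2B intervals in every list. Chromosome 21 held 6 intervals in untreated wild type, 1 in untreated knockout, 3 in treated wild type and 1 in treated knockout, and chromosome 13 held 12, 23, 4 and 11. Chromosome 18 held 51, 36, 28 and 14. Joining the 4 lists gave 29197 separate regions, of which 669 (2.29%) had an interval of every list. Regions with intervals of both untreated lists and of the treated knockout but not of treated wild type numbered 1535 (5.26%), against 472 (1.62%) with treated wild type in place of the treated knockout.

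The highest maxima lay at the same few places in all 4 lists, most of them beside centromeres or their heterochromatin, where reads from satellite repeats are known to pile up. The region at 61968501 to 61970850 of chromosome 7 had 240 times the median maximum of the untreated wild-type list, and 121484251 to 121485500 of chromosome 1 had 97.7 times. The mitochondrial sequence was covered in each list and had 135 times the median in untreated wild type. The interval from the highest called peak of the treated knockout without a counterpart in treated wild type, on chromosome 16 at 46409101, lies near such a place. Several other named intervals without a counterpart lay in 1 Mb windows where every list had intervals, so they need not mark places particular to 1 list. Among these were the windows at 49 Mb of chromosome 5, 42 Mb of chromosome 10, 33 Mb of chromosome 16 and 145 Mb of chromosome 1.

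A hypothesis, with its test fixed before the result was seen, was that intervals of different lists overlap only because they are dense in the same regions. Shifting a whole list by 20 to 500 kb keeps that density, and the overlap at the real positions exceeded the highest of 100 shifts in each of the 4 comparisons, by 1.37 times or more. Regional density alone is therefore unlikely to give the overlap, although it gave a large part of it. After shifts, 21% of untreated wild-type intervals overlapped an untreated knockout interval, against 35.1% at the real positions.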
